A study of Mus musculus with 20 samples.

How the data were processed

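Whole C57BL/6 wild-type mouse embryos without the amnion were collected at 8 stages. Per the labels, embryos were of mixed sex and each sample was total RNA pooled from several of them, extracted with a lipid tissue kit, labelled with biotin in a one-cycle protocol and hybridised to an Affymetrix Mouse Genome 430 2.0 array. The deposited values are of unit intensity: a MAS5 signal per probe set on a linear scale, computed by the authors with MAS5, whose version and settings the labels do not state. On each of the 20 arrays the mean of the values without the lowest and highest 2% was 500.0, so the arrays had been scaled to a common trimmed mean. No other normalization between arrays was found or applied in the main analysis. Arrays give no count depth, and their number limits the precision.

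The values of 45101 probe sets, 64 of them controls, were read. Probe sets annotated with a single gene symbol (34958) were used, and those with several symbols (932) or none (9211) were left out. Entrez identifiers of 34754 were matched to a RefSeq gene table, which changed 0 symbols. A gene with several probe sets was represented by the one with the highest mean log2 value over the 20 arrays. Values were analysed as log2(value + 25.9), where the pseudocount is the median over arrays of the 25th percentile of an array. Of 18193 genes, 14044 were tested, those above the median of the array on at least 2 arrays, and 4149 were left out.

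All 20 arrays were fitted in 1 model with a mean per stage in limma 3.58.1 under R 4.3.3 (lmFit, contrasts, eBayes with trend), with 12 residual degrees of freedom, so that stages with 2 arrays share the estimate of spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested within a comparison. A gene was called at an adjusted p below 0.05 with a change of at least 2-fold. The comparisons were the 7 steps between consecutive stages, E10.5 against E7.5, E18.5 against E10.5, the genes called in both of these in opposite directions, and a moderated F test over the 8 stages. These, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. E18.5 against E12.5 was added afterwards, when control probe sets had separated the arrays of E7.5 to E10.5 from those of E12.5 to E18.5. Profile distances between stages were set against days apart in an exact one-sided Mantel test over all orderings of the stages.

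The 38 gene lists, written from general knowledge of tissue markers, were tested with limma's fry, adjusted over the 38 lists of a comparison, or over all lists and the 7 steps. Some genes stand in more than 1 list. An alternative test, camera with the correlation between genes estimated from the data, compares a list with the other genes. Called members were also counted with p-values adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls of a long comparison and the 3 largest each way of a step, among called genes whose arrays did not overlap between the stages, then up to 4 called members of a list with the largest change, and the 10 most marked genes at E10.5. Symbols of uncharacterised loci and genes measured by probe sets that may cross-hybridise were counted but not named.

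The alternatives were quantile normalization, scaling by the 75th percentile of each array, a pseudocount 4 times smaller or larger, no filter, a filter at the 75th percentile, the mean of all probe sets of a gene, a fit of the arrays of the 2 stages alone, no minimum fold, the replicate number as a block, each array left out in turn, and for the Mantel test Spearman correlation and each stage left out. Fits of a single array set, fits without the first-numbered arrays of E7.5 to E10.5, and Mantel tests of parts of the series were added after the data were seen. Overlaps of calls that share arrays were set beside 20 simulated sets of unchanged genes, held to the p-values and folds of the observed calls, and were counted again with the shared arrays divided between the comparisons. The division was added after the data were seen. The model was tested on simulated data with known changes in 200 of the 14044 genes.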

Results

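Gene expression was measured in wild-type C57BL/6 mouse embryos at 8 stages from embryonic day E7.5 to E18.5, a span that runs from gastrulation and the start of organ formation to the day before birth. The amnion was left out, embryos of both sexes were included, and each sample was RNA pooled from several embryos, hybridised to its own Affymetrix Mouse Genome 430 2.0 array. E7.5, E8.5, E9.5 and E10.5 had 3 arrays each, and E12.5, E14.5, E16.5 and E18.5 had 2 each, 20 in all. The labels call them biological replicates, so p-values measure the spread between these pools, and the number of arrays limits the precision. Each sample was RNA of whole embryos. A change in the share of a tissue and a change of expression within its cells therefore cannot be told apart. Values are MAS5 signals. Changes are differences of log2(signal + 25.9) with the SE of the limma fit, and this scale understates the change of genes with low signal. Signals are means ± SD with n = 3 up to E10.5 and n = 2 from E12.5 on. A gene was called where it changed at least 2-fold at an adjusted p below 0.05, and "rose" and "fell" are used only of called genes and lists. The test of a gene list asks whether its members moved one way on balance, and does not compare the list with other genes. Counts of list members are of those tested. Many lists were longer as written, and genes without a usable probe set or under the signal filter are not counted. Values given "with an estimated correlation" come from camera, which does make that comparison and also estimates the correlation between genes. A call lost there can reflect either difference.

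Signal levels and control probe sets separated the 20 arrays into a pair of sets. The median signal of an array was 67.2 to 91.1 on the 12 arrays of E7.5 to E10.5 and 156 to 178 on the 8 arrays of E12.5 to E18.5. A poly-A spike-in control, the dap transcript read by its middle probe set, gave 15.4 to 123 on the first set and 1985 to 3013 on the second. The geometric mean of the poly-A controls was 6.86 to 38.1 on the first set and 371 to 527 on the second. On the first set this lay around the 25th percentile of an array, which was 18.6 to 28.4. Whether the controls had been added to the first set cannot be told from these values. No stage had arrays in both sets, so for every difference between E10.5 and a later stage the array set and the stage cannot be told apart. Comparisons within E7.5 to E10.5 and within E12.5 to E18.5 stay inside a set.

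**Figure D1:**
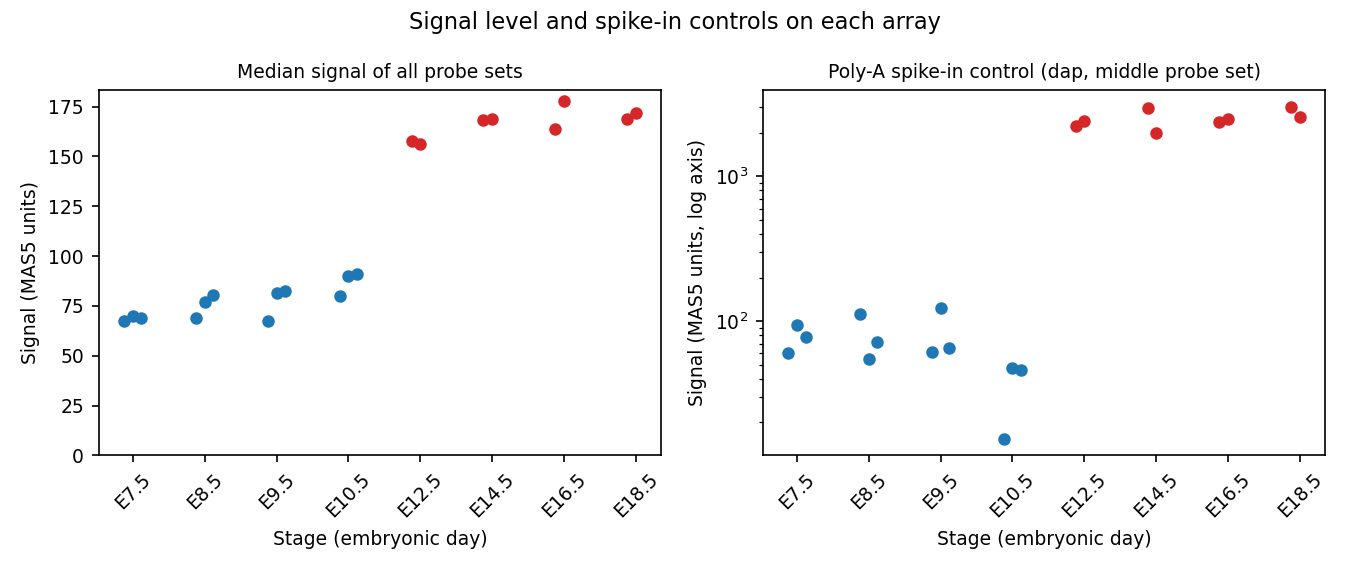
Median signal of all probe sets (left, MAS5 units) and signal of the dap spike-in control (right, MAS5 units on a log axis) against stage, with a point for each of the 20 arrays. All 8 arrays of E12.5 to E18.5 lie above all 12 arrays of E7.5 to E10.5 in both panels, with the control at 1985 or more against 123 or less.

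Most of the genes tested differed somewhere along the series, and the stages lay in the order of their age. In a moderated F test over the 8 stages, 9542 of 14044 genes (67.9%) were called. From E7.5 to E18.5, in order of age, 1824, 743, 419, 624, 1367, 848, 876 and 2841 of these had their highest mean at the stage. The 1367 at E12.5 fall on the first stage of the second array set. The distance between stage profiles (1 minus the Pearson correlation of mean log2 signals over all genes tested) grew with the days between them. Over the 28 pairs of stages Pearson's r was 0.98 and Spearman's rho 0.98, each with a one-sided p of 2.5e-05 in an exact Mantel test, the smallest that the orderings of 8 stages allow. Without E16.5 and E18.5 r was 0.95 (exact p = 0.0014). Within E7.5 to E10.5 it was 0.92 and within E12.5 to E18.5 it was 0.99. Each of these had an exact p of 0.083, the smallest that 24 orderings of 4 evenly spaced stages allow. Replicate arrays of a stage correlated at 0.977 to 0.991. Between stage means, the step from E7.5 to E8.5 covered a distance of 0.0517, against 0.0229 and 0.0201 for the next steps of a day each. Between single arrays of the neighbouring stages the mean distances were 0.0638, 0.0352 and 0.0324 in the same order. Replicate arrays of these stages lay at most 0.0225, 0.0206 and 0.0197 apart.

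The first long comparison, E10.5 against E7.5, spans early organ formation and lies within the first array set. Genes of neurons, heart and connective tissue rose, while genes of the extraembryonic endoderm, the trophoblast and the undifferentiated epiblast fell. How much extraembryonic or maternal tissue each sample held was not tested. For falls of such genes, here and at the single steps, a change in the tissue collected and a change in expression cannot be told apart. Col3a1, a fibrillar collagen of loose connective tissue, rose from 56.1 ± 15.6 to 14924 ± 920.0 (log2 change 7.53 ± 0.15, adjusted p = 1.5e-18). Zic1, a zinc finger factor of the dorsal neural tube, rose by 7.10 ± 0.16, and Hba-x, an embryonic alpha-like globin, by 6.91 ± 0.33 to 42184 ± 6499. Spink1, a trypsin inhibitor, fell by 7.94 ± 0.20 on the log2 scale, from 15239 ± 2301 to 37.5 ± 17.7 (adjusted p = 3.4e-17). In all, 2251 genes rose and 1052 fell, or 4811 and 3339 with no minimum fold. With each array scaled by its 75th percentile the split was 1860 to 1449, and this scaling moved the median change of all genes from 0.11 to -0.06. Quantile normalization moved it to 0.01.

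Among the other largest rises, Dcx, a microtubule protein of migrating neurons, changed by 6.07 ± 0.22, and Nhlh2, a helix-loop-helix factor of young neurons, by 5.70 ± 0.24. Nr2f1, a nuclear receptor of the developing nervous system, rose by 6.50 ± 0.16 and Zfhx4 by 5.83 ± 0.20. Lum, a proteoglycan that binds collagen, rose by 5.63 ± 0.16, Hemgn, a nuclear protein of blood progenitors, by 5.56 ± 0.20, and Myl2, the ventricular myosin light chain, by 5.39 ± 0.18. On the falling side, Apoc2, an apolipoprotein that activates lipoprotein lipase, fell by 7.61 ± 0.37. Amn and Cubn, which together form an endocytic receptor of absorptive epithelia, fell by 7.40 ± 0.25 and 6.57 ± 0.54. Phlda2, an imprinted gene that limits placental growth, fell by 7.13 ± 0.14, Trap1a by 7.11 ± 0.34, and Rhox5, an X-linked homeobox gene of the extraembryonic lineages, by 6.71 ± 0.16. The carbonic anhydrases Car7 and Car4 fell by 6.49 ± 0.26 and 6.36 ± 0.12, and the sulfate transporter Slc13a4 by 6.48 ± 0.39. All these had adjusted p of 1.8e-09 or less.

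The lists of the earliest lineages fell. In the pluripotency and epiblast list 10 of 16 genes fell and 1 rose (median -2.94, adjusted p = 9.1e-11), among them Pou5f1, the Oct4 factor of the epiblast, from 2765 ± 824 to 44.3 ± 35.2, L1td1, which fell by 5.07 ± 0.20, and Zfp42, which fell by 3.8 ± 0.30. Of the visceral and yolk sac endoderm list 15 of 16 fell (median -4.0, adjusted p = 4.7e-12), including Hnf4a, a nuclear receptor of endoderm, by 4.61 ± 0.27. All 6 tested trophoblast genes fell (median -3.91, adjusted p = 6.7e-10), with Elf5, a trophoblast stem cell factor, down from 2487 ± 483 to 27.6 ± 34.6 and Ascl2 by 5.0 ± 0.30. In the primitive streak and early mesendoderm list 9 of 15 fell and 1 rose (median -1.37, adjusted p = 2.4e-09). Foxh1, a partner of nodal signalling, fell by 4.07 ± 0.36 and Mixl1, a streak homeobox factor, by 3.58 ± 0.41. The intestine list also fell, in 6 of 15 genes (median -0.19, adjusted p = 7.1e-10). Among the members that fell, those named here are also genes of the posterior embryo or of extraembryonic endoderm, a grouping that was not tested. Cdx1 fell by 5.20 ± 0.22, Cdx2 by 4.59 ± 0.31, Vil1, an actin bundler of microvilli, by 5.12 ± 0.27 and the lipid-binding Fabp1 by 4.45 ± 0.28.

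Patterning and nervous system lists rose. All 11 tested genes of Hox paralogues 9 to 13 rose (median 2.33, adjusted p = 1.5e-12), with Hoxa9 at 3.40 ± 0.13 and Hoxd10 at 3.40 ± 0.21, as did 7 of 8 of paralogues 5 to 8 (median 2.39, adjusted p = 1.1e-12), led by Hoxc5 at 4.24 ± 0.24. Of paralogues 1 to 4, 6 of 10 rose and 1 fell (median 1.60, adjusted p = 6.8e-10, adjusted p = 0.11 with an estimated correlation): Hoxc4 rose by 3.62 ± 0.17 while Hoxb1, a hindbrain patterning gene, fell by 2.74 ± 0.16. The limb and pharyngeal arch list rose in 14 of 22 genes (median 1.77, adjusted p = 1.2e-12), with the mesenchymal homeobox gene Prrx1 at 4.70 ± 0.15. In the somite list 6 of 15 rose and 3 fell (median 0.52, adjusted p = 6.8e-10, adjusted p = 0.18 with an estimated correlation): Tbx18 rose by 3.56 ± 0.22, and Tbx6, a factor of unsegmented mesoderm, fell by 2.95 ± 0.18. Of the neuron list 18 of 20 rose (median 2.65, adjusted p = 1.5e-12), including the RNA-binding Elavl4 at 5.19 ± 0.17 and the tubulin Tubb3 at 4.13 ± 0.10. Of the neural progenitor list 12 of 15 rose (median 2.29, adjusted p = 1.1e-13), with the proneural factors Neurog2 at 4.62 ± 0.20 and Neurog1 at 4.59 ± 0.25. The glia list rose in 4 of 10 genes with 1 fall (median 0.66, adjusted p = 6.8e-07, adjusted p = 0.24 with an estimated correlation), among them Sox10, a neural crest factor, at 2.70 ± 0.27.

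Muscle, matrix and blood lists rose as well. The cardiac muscle list rose in 14 of 17 genes with 1 fall (median 3.14, adjusted p = 7.9e-13), with the myosins Myh6 at 5.37 ± 0.15 and Myh7 at 4.79 ± 0.12. The skeletal muscle list rose in 14 of 21 (median 1.61, adjusted p = 2.6e-15), with Myl1 at 4.37 ± 0.27 and the myogenic factor Myog at 3.28 ± 0.22. Fibrillar collagen and matrix genes rose in 16 of 18 (median 2.79, adjusted p = 2.6e-15), with the matrix protein Postn at 4.75 ± 0.13. Cartilage genes rose in 9 of 17 (median 1.01, adjusted p = 2.6e-12), led by the collagen Col2a1 at 4.63 ± 0.30, and bone genes in 3 of 13 with 1 fall (median 0.05, adjusted p = 1.2e-07, adjusted p = 0.83 with an estimated correlation), led by Col1a2 at 4.11 ± 0.11. All 3 primitive erythroid globins rose (median 6.91, adjusted p = 1.5e-11, adjusted p = 0.092 with an estimated correlation). The erythroid list rose in 11 of 15 (median 2.08, adjusted p = 3.9e-09, adjusted p = 0.17 with an estimated correlation), with Alas2, the first enzyme of haem synthesis in red cells, at 4.33 ± 0.21. The endothelial list rose in 9 of 17 with 2 falls (median 1.07, adjusted p = 1.5e-07, adjusted p = 0.20 with an estimated correlation): the sialomucin Emcn rose by 4.83 ± 0.23 and Etv2, an early factor of blood vessel progenitors, fell by 2.66 ± 0.26. The myeloid and lymphoid list rose in 7 of 17 (median 0.58, adjusted p = 1.3e-07, adjusted p = 0.24 with an estimated correlation), with the macrophage receptor Csf1r at 2.81 ± 0.20.

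Lists of metabolism and growth were called in both directions. The hypoxia list fell in 4 of 13 (median -0.45, adjusted p = 4.1e-10), with the glucose transporter Slc2a1 down by 1.99 ± 0.10. The Lin28 axis list fell in 4 of 10 (median -0.43, adjusted p = 4.1e-07, adjusted p = 0.20 with an estimated correlation), with Lin28a, which blocks maturation of let-7 microRNAs, down by 3.77 ± 0.20. The cell cycle list fell (median -0.26, adjusted p = 3.8e-04, adjusted p = 0.20 with an estimated correlation) with 1 call each way in 20. Imprinted growth genes rose in 5 of 13 with 2 falls (median 0.74, adjusted p = 3.6e-05, adjusted p = 0.47 with an estimated correlation): the cyclin kinase inhibitor Cdkn1c rose by 2.00 ± 0.13 against the fall of Phlda2. Immediate early and heat shock genes rose in 2 of 13 with 3 falls (median 0.06, adjusted p = 4.0e-05, adjusted p = 0.96 with an estimated correlation, where the direction of the test turned). In this list Jun rose by 2.87 ± 0.13 and Fos fell by 1.80 ± 0.20. Rises on balance were also called for fatty acid oxidation, with 1 rise and 1 fall in 14 (median 0.30, adjusted p = 0.0019, adjusted p = 0.74 with an estimated correlation), epidermis, with 3 rises and 2 falls in 22 (median 0.21, adjusted p = 0.0067, adjusted p = 0.89 with an estimated correlation), pancreas, with 3 rises and 1 fall in 13 (median 0.29, adjusted p = 0.034, adjusted p = 0.996 with an estimated correlation), and maternal decidua, with 5 rises and 3 falls in 9 (median 1.53, adjusted p = 0.0015, adjusted p = 0.96 with an estimated correlation). In the decidua list Hoxa10 and Wnt4, which the embryo also expresses, rose by 2.33 ± 0.26 and 1.80 ± 0.15, and Prl8a2, a prolactin of the decidua, fell by 4.01 ± 0.36. The epidermis list held a rise of Trp63, the p63 factor of surface epithelium, by 2.35 ± 0.18 and a fall of the transglutaminase Tgm1 by 2.41 ± 0.31.

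Not called were liver (median 0.08, adjusted p = 0.96), lung (median 0.05, adjusted p = 0.20), kidney (median 0.09, adjusted p = 0.37), adipocyte (median 0.22, adjusted p = 0.16), lens crystallins (median -0.14, adjusted p = 0.57) and common reference genes (median -0.08, adjusted p = 0.49). For liver, kidney, lens and reference genes the median, mean and test differed in sign, and within the liver list albumin (Alb) rose by 4.11 ± 0.29 and fibrinogen (Fgb) fell by 3.03 ± 0.16. In all, 32 of 38 lists were called, 23 up and 9 down, and 15 of them with an estimated correlation. Adjusted over the list alone, each list had the same number of rises and falls as over all genes. Quantile normalization ended the calls of the decidua (adjusted p = 0.45), epidermis (0.19), pancreas (0.70) and cell cycle (0.18) lists. Scaling by the 75th percentile ended those of decidua (0.076), epidermis (0.085), pancreas (0.16), imprinted growth genes (0.053) and fatty acid oxidation, whose test turned (0.98). The decidua call also ended with the stricter filter (median 0.68, adjusted p = 0.33) and with no filter, where the median was -0.30 (0.085). Arrays numbered 2 and 3 only ended those of epidermis (0.065) and immediate early genes (0.073). The pancreas call ended with the stricter filter, whose test turned (median 0.02, adjusted p = 0.88), with the mean of all probe sets (0.11), with only the first array set in the fit (0.145), and without E7.5 replicate 1 (median 0.15, adjusted p = 0.11) or 3 (0.19, 0.074) or E10.5 replicate 2 (0.06, 0.18) or 3 (0.12, 0.081). Adipocyte genes were called without E7.5 replicate 2 (median 0.40, adjusted p = 0.0060) and lung genes without E7.5 replicate 3 (0.21, 0.043). Other settings called kidney after quantile normalization (median -0.09, adjusted p = 0.0095) and adipocyte with the stricter filter (0.0028) and a pseudocount 4 times larger (0.041). Reference genes were called with scaling by the 75th percentile (0.0036) and the mean of all probe sets (0.021).

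The steps of a day each show when these groups moved. Heart genes rose at the first step: from E7.5 to E8.5, 15 of 17 cardiac genes rose and 1 fell (median 3.64, adjusted p = 4.8e-12), and the largest rises were Hoxb5os, an RNA from the strand opposite Hoxb5, at 6.45 ± 0.15, the atrial myosin Myh6 at 6.03 ± 0.15 and cardiac actin Actc1 at 5.90 ± 0.12. Embryonic globins rose at the same step (median 5.28, adjusted p = 9.7e-10), as did Hox paralogues 1 to 4 in 7 of 10 (median 1.62, adjusted p = 1.1e-10) and 5 to 8 in 6 of 8 (median 2.06, adjusted p = 1.3e-11). Dnmt3l, a cofactor of DNA methylation, fell by 4.92 ± 0.36, Elf5 by 4.86 ± 0.36 and Mageb16 by 4.46 ± 0.32, all 6 tested trophoblast genes fell (median -3.14, adjusted p = 1.6e-08) and 15 of 16 visceral endoderm genes fell (median -2.09, adjusted p = 1.6e-08). At this step 881 genes rose and 693 fell. The split was 679 to 731 after quantile normalization, where falls outnumber rises, and 812 to 800 with scaling by the 75th percentile.

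From E8.5 to E9.5, 349 genes rose and 236 fell. Epha3, an ephrin receptor, rose by 3.42 ± 0.20, Neurog1 by 3.41 ± 0.25 and Dcx by 3.30 ± 0.22. Prl8a2 fell by 4.50 ± 0.36, Spink1 fell by 4.15 ± 0.20 and Apoc2 by 4.0 ± 0.37, and 13 of 16 visceral endoderm genes fell (median -2.52, adjusted p = 4.2e-08). The erythroid list rose in 9 of 15 (median 1.28, adjusted p = 6.0e-07). From E9.5 to E10.5, 442 genes rose and 72 fell, a split of 314 to 102 after quantile normalization and of 1680 to 960 with no minimum fold. This was the step of the neuron list, of which 16 of 20 rose (median 2.00, adjusted p = 8.3e-10). Rufy3 rose by 3.42 ± 0.29, the zinc finger factor Bcl11a by 3.41 ± 0.23 and Slc17a6, the transporter that loads glutamate into synaptic vesicles, by 3.21 ± 0.25. Prtg, a cell surface protein of the immunoglobulin family, fell by 3.06 ± 0.13, the nuclear receptor Nr6a1 by 2.67 ± 0.19 and Car4 by 2.55 ± 0.12. Of the 5 probe sets of Nr6a1, 1 moved the other way, by 0.64.

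**Figure D2:**
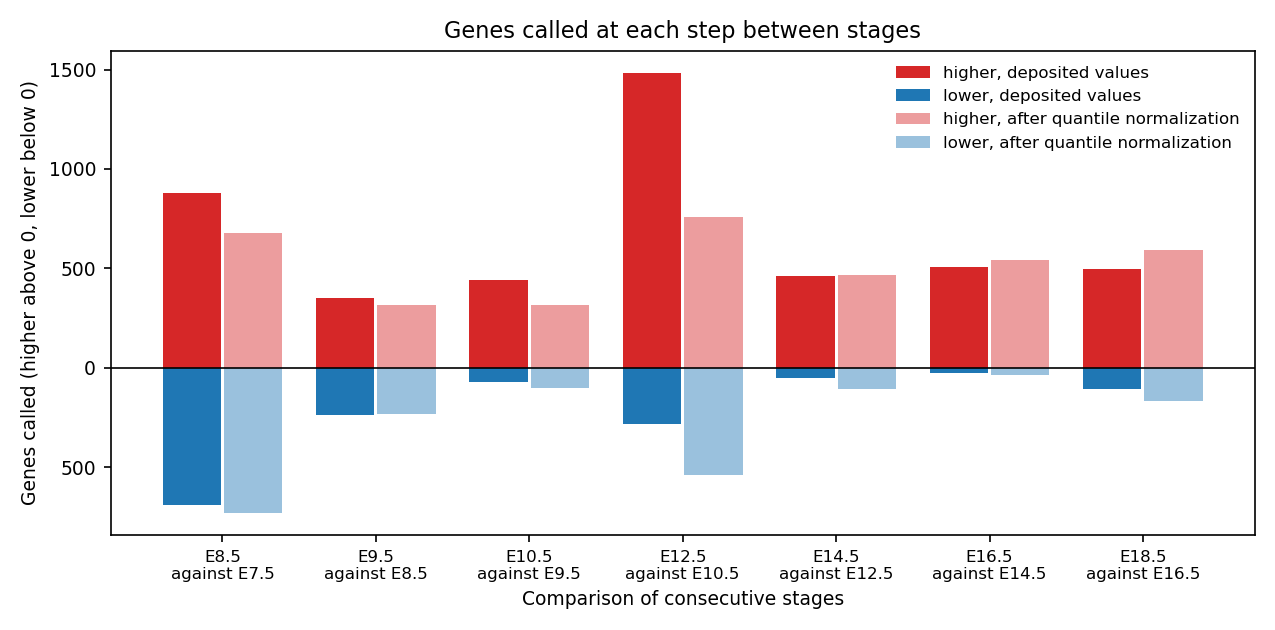
Number of genes called at each of the 7 steps between consecutive stages, with rises above 0 and falls below 0, in dark bars for the deposited values and light bars after quantile normalization. The step from E10.5 to E12.5, between the array sets, has 1484 rises and 284 falls in the deposited values and 756 and 539 after quantile normalization.

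From E10.5 to E12.5 the matrix and liver lists rose and the Lin28 axis and cell cycle lists fell, in a step of 2 days that is also the change of array set. S100a8, a calcium-binding protein of neutrophils, rose by 4.89 ± 0.39, the X-linked ubiquitin ligase Mid1 by 4.73 ± 0.28, and Neurod6, a factor of cortical neurons, by 4.49 ± 0.23. Sall4, a zinc finger factor of stem cells, fell by 3.62 ± 0.26, Lin28a fell by 3.59 ± 0.23 and Igdcc3 by 3.49 ± 0.12, though 1 of the 3 probe sets of Igdcc3 moved by 0.98. Matrix genes rose in 13 of 18 (median 1.63, adjusted p = 1.3e-10), liver genes in 13 of 20 with 1 fall (median 1.79, adjusted p = 1.1e-08), and lens crystallins in 7 of 9 (median 1.45, adjusted p = 2.7e-07). Neuron genes rose in 8 of 20 (median 0.77, adjusted p = 7.3e-06, adjusted p = 0.14 with an estimated correlation). The Lin28 axis fell in 5 of 10 (median -1.01, adjusted p = 6.1e-10) and the cell cycle list in 3 of 20 (median -0.80, adjusted p = 4.4e-10). The deposited values gave 1484 rises and 284 falls (83.9% rises), and quantile normalization 756 and 539 (58.4%), with 883 genes called in both. Scaling by the 75th percentile gave 928 and 881 (51.3%). The median change of all genes was 0.12, and -0.11 with either. With no minimum fold the deposited values gave 3715 and 2950 (55.7%).

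The second long comparison, E18.5 against E10.5, covers the growth of the fetus and crosses the array sets. Lists of skin, skeletal muscle, fat, gut, liver, and myeloid and lymphoid genes rose, and the embryonic globin, Lin28 axis and cell cycle lists fell. Fabp4, the fatty acid carrier of adipocytes, rose from 26.5 ± 4.30 to 30347 ± 1616 (log2 change 9.18 ± 0.29, adjusted p = 1.6e-15). Hba-x fell by 8.77 ± 0.37 on the log2 scale, from 42184 ± 6499 to 70.4 ± 10.9 (adjusted p = 1.0e-13). In all, 3381 genes rose and 1761 fell, a split of 2584 to 2485 after quantile normalization and of 2901 to 2471 with each array scaled by its 75th percentile. With no minimum fold it was 5170 to 4588. Quantile normalization moved the median change of all genes from 0.08 to -0.16.

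Because that comparison crosses the sets, E18.5 was also compared with E12.5 inside the second set, a comparison chosen after the data were seen. There 2139 genes rose and 905 fell. With no minimum fold 3369 rose and 4096 fell, and the median change of all genes was -0.09. The 10 largest rises included epidermal genes: Hrnr (hornerin) rose by 8.58 ± 0.27, Dmkn (dermokine) by 8.51 ± 0.33, Calm4, a calmodulin-like protein of skin, by 8.47 ± 0.47 and Flg (filaggrin) by 8.15 ± 0.35, with Krtdap at 7.86 ± 0.33. Ckm, muscle creatine kinase, rose by 8.29 ± 0.46, Ucp1, the uncoupling protein of brown fat, by 8.18 ± 0.49, Sftpc, a lung surfactant protein, by 8.02 ± 0.42, Ctrb1, a pancreatic chymotrypsinogen, by 8.02 ± 0.40 and Smgc, a salivary gland protein, by 7.67 ± 0.35. Hba-x fell by 7.89 ± 0.40, Hmga2, a chromatin protein and let-7 target, by 4.14 ± 0.22, Nhlh2 by 3.94 ± 0.30, Serpina6, the plasma carrier of corticosteroids, by 3.93 ± 0.32, Ppp1r17 by 3.52 ± 0.30 and Neurog2 by 3.23 ± 0.24. The axon guidance receptors Robo3 and Dcc fell by 3.10 ± 0.36 and 3.00 ± 0.17, St18 by 2.99 ± 0.41 and Lhx9 by 2.97 ± 0.32. All these had adjusted p of 4.2e-06 or less.

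Against E10.5, the largest rises besides Fabp4 were Stfa3, a cysteine protease inhibitor, by 9.25 ± 0.29, Fabp1 by 9.16 ± 0.31, the perinatal myosin Myh8 by 9.11 ± 0.24, the neutrophil proteins S100a8 and S100a9 by 8.87 ± 0.39 and 8.67 ± 0.30, Ckm by 8.84 ± 0.42, Dmkn by 8.74 ± 0.30, Atp1b4 by 8.64 ± 0.25 and Ahsg, the plasma protein fetuin-A, by 8.64 ± 0.24. After Hba-x the largest falls were Igdcc3 (-5.22 ± 0.12, with 1 of its 3 probe sets at 0.53), Hmga2 (-5.22 ± 0.20), Sall4 (-4.87 ± 0.26) and Lin28a (-4.51 ± 0.23). Neurog1 fell by 4.38 ± 0.28, the retinoic acid binding proteins Crabp2 and Crabp1 by 4.32 ± 0.09 and 4.14 ± 0.10, Ppp1r17 by 4.31 ± 0.28 and Nhlh2 by 3.93 ± 0.27.

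Lists of late tissues rose both against E10.5 and, within the set, against E12.5. Epidermis genes rose in 21 of 22 against E10.5 (median 5.37, adjusted p = 6.6e-15) and 21 of 22 against E12.5 (median 4.85, adjusted p = 1.7e-13). Skeletal muscle genes rose in 20 of 21 (median 4.67, adjusted p = 1.0e-18) and 18 of 21 (median 3.92, adjusted p = 1.7e-17), with the fast troponin Tnnt3 at 6.26 ± 0.27 against E12.5. Adipocyte genes rose in 11 of 11 in both (median 4.2, adjusted p = 3.3e-18, and median 4.26, adjusted p = 1.7e-17), with the hormone gene Adipoq at 7.66 ± 0.36. Intestine genes rose in 15 of 15 in both (median 4.47, adjusted p = 5.1e-14, and median 4.26, adjusted p = 7.6e-13), with Fabp2, a fatty acid carrier of enterocytes, at 7.23 ± 0.27. Liver genes rose in 19 of 20 (median 5.54, adjusted p = 3.6e-15) and 18 of 20 (median 3.72, adjusted p = 4.7e-13) with 1 fall each, and haptoglobin (Hp) changed by 6.77 ± 0.26. Pancreas genes rose in 11 of 13 in both (median 4.68, adjusted p = 1.8e-13, and median 4.33, adjusted p = 7.6e-13), with the elastase Cela2a at 7.05 ± 0.36. Bone genes rose in 12 of 13 (median 3.81, adjusted p = 1.9e-14) and 13 of 13 (median 2.87, adjusted p = 7.6e-13), with the collagenase Mmp13 at 7.01 ± 0.34. Lung genes rose in 10 of 11 (median 4.48, adjusted p = 7.7e-11) and 9 of 11 (median 3.27, adjusted p = 1.3e-09), with Scgb3a2, a secretory protein of airways, at 6.56 ± 0.33.

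Myeloid and lymphoid genes rose in 17 of 17 against E10.5 (median 3.52, adjusted p = 2.1e-13) and 16 of 17 against E12.5 (median 3.04, adjusted p = 1.1e-10), with S100a9 at 4.29 ± 0.33 in the latter. Matrix genes rose in 17 of 18 (median 3.81, adjusted p = 3.6e-15) and 16 of 18 (median 1.96, adjusted p = 5.0e-12), with the dermal protein Dpt at 5.25 ± 0.33. Cartilage genes rose in 13 of 17 with 2 falls (median 3.11, adjusted p = 5.1e-14) and in 10 of 17 with 1 fall (median 1.36, adjusted p = 1.3e-10), with Col10a1, a collagen of hypertrophic cartilage, at 5.29 ± 0.37. Fatty acid oxidation genes rose in 13 of 14 in both (median 1.79, adjusted p = 2.1e-13, and median 1.89, adjusted p = 7.6e-13), with the dehydrogenase Acadm at 2.49 ± 0.08 and the nuclear receptor Ppara at 3.63 ± 0.45. Lens crystallins rose in 9 of 9 (median 4.06, adjusted p = 5.6e-12) and 8 of 9 (median 1.80, adjusted p = 6.8e-09), or 9 of 9 adjusted over the list alone. That was the only list in either comparison whose count differed when adjusted over the list alone. Hypoxia genes rose in 3 of 13 (median 0.49, adjusted p = 1.0e-09, adjusted p = 0.097 with an estimated correlation) and 4 of 13 (median 0.74, adjusted p = 4.4e-10), with Ndrg1 at 2.83 ± 0.16. Immediate early and heat shock genes rose in 6 of 13 with 1 fall (median 0.89, adjusted p = 2.9e-09, adjusted p = 0.14 with an estimated correlation) and in 5 of 13 (median 0.69, adjusted p = 1.1e-07), with the chaperone Hspa1b at 2.45 ± 0.27.

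Proliferation and embryonic patterning lists fell in both comparisons. Whether these falls, or the late falls of other lists, reflect a smaller share of a tissue in the whole embryo was not tested. Cell cycle genes fell in 20 of 20 against E10.5 (median -1.76, adjusted p = 4.9e-15) and 13 of 20 against E12.5 (median -1.11, adjusted p = 5.0e-12), with the spindle checkpoint kinase Bub1 down by 1.44 ± 0.11 in the latter. The Lin28 axis fell in 8 of 10 (median -2.84, adjusted p = 6.6e-15) and 7 of 10 (median -1.26, adjusted p = 6.2e-12), with the RNA-binding Igf2bp1 down by 2.59 ± 0.11. Neural progenitor genes fell in 9 of 15 (median -1.57, adjusted p = 1.0e-11) and 10 of 15 (median -1.21, adjusted p = 6.4e-11), with Sox2 down by 2.24 ± 0.14. The Hox lists fell against E12.5 in 6 of 10 of paralogues 1 to 4 (median -1.39, adjusted p = 1.7e-09), 7 of 8 of 5 to 8 (median -1.42, adjusted p = 4.8e-09) and 8 of 11 of 9 to 13 (median -1.59, adjusted p = 1.5e-09), where Hoxd13, a gene of digits and genital tubercle, fell by 2.95 ± 0.28. Against E10.5 they fell in 10 of 10, 4 of 8 and 8 of 11 (adjusted p = 1.5e-10, 6.5e-09 and 2.3e-09). Limb and pharyngeal arch genes fell in 9 of 22 (median -0.79, adjusted p = 2.7e-10) and 11 of 22 (median -1.04, adjusted p = 8.2e-10), and somite genes in 8 of 15 with 1 rise (median -1.01, adjusted p = 1.6e-10) and 7 of 15 (median -0.81, adjusted p = 1.2e-09). All 3 embryonic globins fell in both (median -8.77, adjusted p = 3.8e-13, and median -7.89, adjusted p = 5.0e-12).

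Several lists were called without holding in the test with an estimated correlation, which also compares a list with the other genes. Visceral and yolk sac endoderm genes, many of which fetal liver and gut also express, rose in 12 of 16 with 2 falls (median 3.25, adjusted p = 2.2e-08, adjusted p = 0.20 with an estimated correlation) and in 11 of 16 (median 1.86, adjusted p = 4.4e-06, adjusted p = 0.16 with an estimated correlation), with the gap junction gene Gjb1 at 4.47 ± 0.39. Glia genes rose in 5 of 10 with 1 fall (median 1.13, adjusted p = 4.9e-06, adjusted p = 0.23 with an estimated correlation) and 4 of 10 with 2 falls (median 0.82, adjusted p = 0.0010, adjusted p = 0.28 with an estimated correlation), with S100b at 2.20 ± 0.37. Endothelial genes rose in 4 of 17 (median 0.75, adjusted p = 9.2e-06, adjusted p = 0.26 with an estimated correlation) and 3 of 17 (median 0.51, adjusted p = 4.3e-05, adjusted p = 0.13 with an estimated correlation), with the adhesion molecule Pecam1 at 1.34 ± 0.18. Cardiac genes rose in 4 of 17 with 1 fall (median 0.19, adjusted p = 0.040, adjusted p = 0.82 with an estimated correlation) and 6 of 17 with 1 fall (median 0.59, adjusted p = 0.0010, adjusted p = 0.35 with an estimated correlation), led by titin (Ttn) at 3.05 ± 0.26. Kidney genes rose in 5 of 9 (median 1.57, adjusted p = 3.8e-05, adjusted p = 0.32 with an estimated correlation) and 4 of 9 (median 0.66, adjusted p = 0.0019, adjusted p = 0.28 with an estimated correlation), with the salt transporter Slc12a1 at 2.79 ± 0.48. Pluripotency genes fell in 5 of 16 (median -0.11, adjusted p = 7.2e-06, adjusted p = 0.34 with an estimated correlation) and 3 of 16 (median -0.24, adjusted p = 2.5e-04, adjusted p = 0.35 with an estimated correlation), with Otx2 down by 1.96 ± 0.21. Streak and mesendoderm genes fell in 5 of 15 (median -0.48, adjusted p = 3.9e-05, adjusted p = 0.26 with an estimated correlation) and 4 of 15 (median -0.13, adjusted p = 4.9e-05, adjusted p = 0.26 with an estimated correlation), with Lhx1 down by 2.51 ± 0.20. Imprinted growth genes rose in 1 of 13 (median 0.22, adjusted p = 0.0018, adjusted p = 0.79 with an estimated correlation), maternal decidua genes in 3 of 9 with 1 fall (median 0.75, adjusted p = 2.0e-05, adjusted p = 0.34 with an estimated correlation), and trophoblast genes in 2 of 6 (median 0.58, adjusted p = 0.048, adjusted p = 0.79 with an estimated correlation), all against E10.5.

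Neuron genes fell within the second set, in 7 of 20 (median -0.68, adjusted p = 2.6e-06, adjusted p = 0.17 with an estimated correlation), with the intermediate filaments Ina and Nefm down by 2.23 ± 0.16 and 1.65 ± 0.19. Against E10.5 the list was not called, with 7 rises and 5 falls in 20 (median -0.01, adjusted p = 0.36). With scaling by the 75th percentile it was (median -0.22, adjusted p = 0.013). Gad1, which makes the transmitter GABA, rose by 3.16 ± 0.25 and Isl1, a factor of motor neurons, fell by 2.24 ± 0.12. Erythroid genes fell within the set in 5 of 15 (median -0.79, adjusted p = 6.0e-04, adjusted p = 0.28 with an estimated correlation), with the blood group gene Kel down by 1.63 ± 0.25, and were not called against E10.5 (median 0.03, adjusted p = 0.48). Within the set, maternal decidua (median 0.38, adjusted p = 0.33), trophoblast (median 0.60, adjusted p = 0.076) and imprinted growth genes (median -0.09, adjusted p = 0.095) were not called. With only the second array set in the fit trophoblast (adjusted p = 9.0e-04) and decidua (0.019) were called. Decidua was also called with a pseudocount 4 times larger (0.047) and the mean of all probe sets (0.028), and imprinted genes with that mean (0.029). For imprinted genes there, and for neuron genes against E10.5, the median and mean differed in sign. In all, 35 of 38 lists were called against E10.5 (24 up, 11 down) and 34 against E12.5 (21 up, 13 down), of which 22 and 24 were called with an estimated correlation. Quantile normalization ended the calls of kidney (adjusted p = 0.080) and trophoblast genes, whose test turned (0.51), against E10.5, and scaling by the 75th percentile those of trophoblast (0.16), cardiac (0.67) and imprinted growth genes (0.49). A pseudocount 4 times smaller (0.069), no filter (0.085) and the mean of all probe sets (0.33) ended the trophoblast call. The cardiac call against E10.5 also ended with a pseudocount 4 times smaller (0.092) and without E10.5 replicate 1 (median 0.17, adjusted p = 0.087) or 2 (0.05, 0.55) or E18.5 replicate 1 (0.32, 0.098) or 2 (0.06, 0.24). The trophoblast call also ended without E10.5 replicate 2 (median 0.48, adjusted p = 0.12) or 3 (0.62, 0.055) or E18.5 replicate 1 (0.36, 0.24) or 2 (0.79, 0.080). Erythroid genes were called without E10.5 replicate 3 (median 0.14, adjusted p = 0.014).

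**Figure D3:**
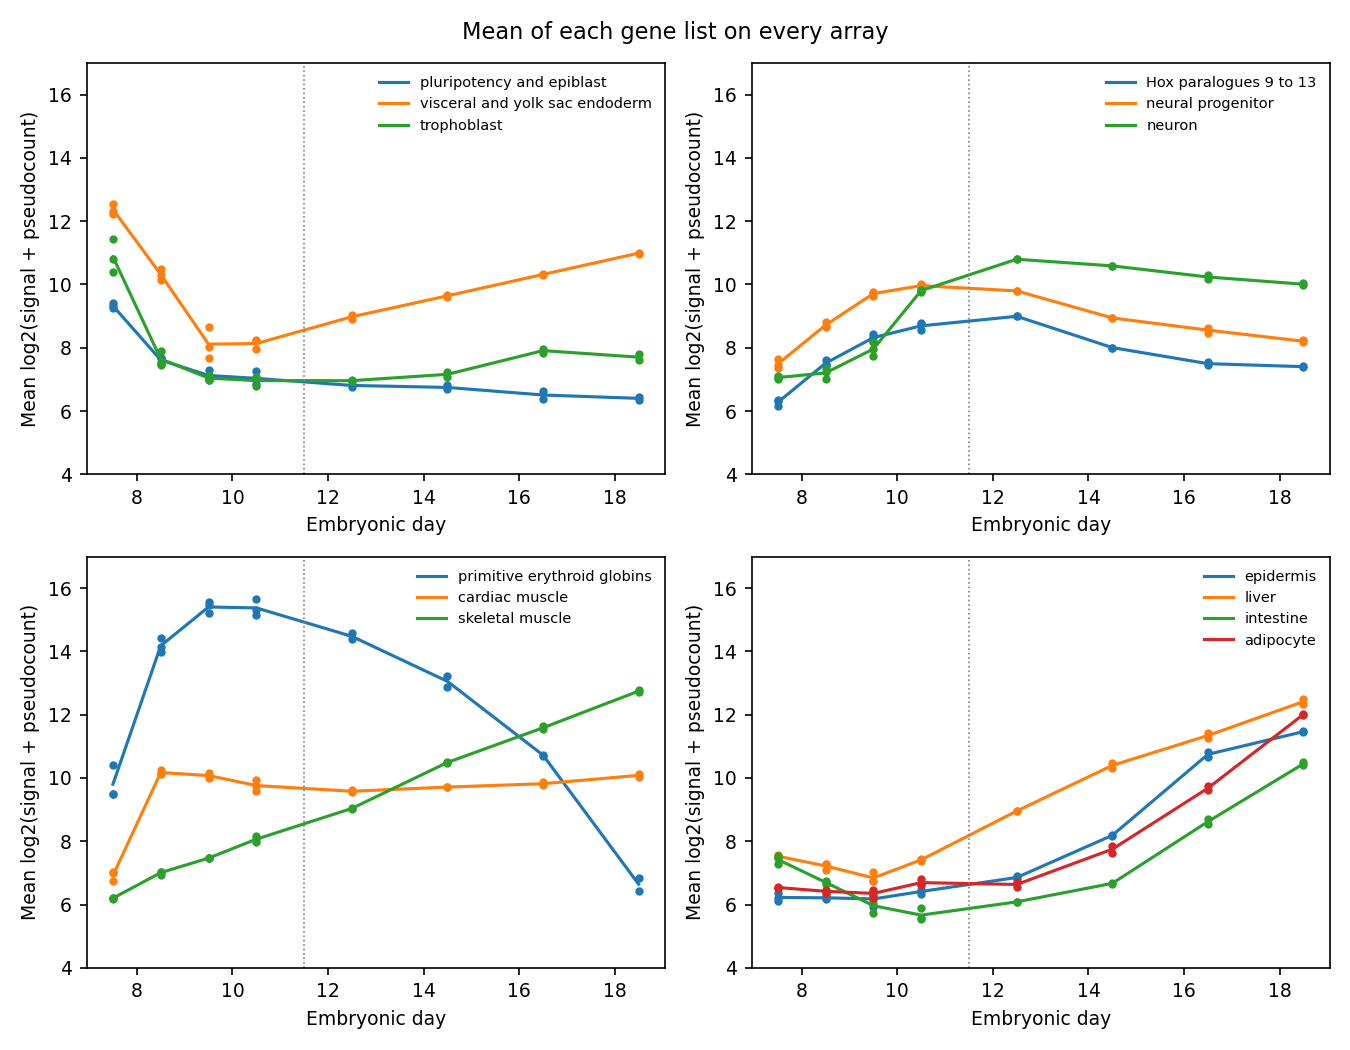
Mean log2(signal + pseudocount) over the members of 13 gene lists against embryonic day, with a point for each of the 20 arrays and lines through the stage means; the dotted line separates the array sets. Cardiac genes rise between E7.5 and E8.5, neuron genes between E9.5 and E10.5 and epidermis genes between E14.5 and E16.5, while embryonic globins fall from E12.5 on.

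Within the second set, the epidermis, intestine and adipocyte lists rose at each of the 3 steps. From E12.5 to E14.5, 460 genes rose and 52 fell, or 918 and 545 with no minimum fold. Dmkn rose by 4.74 ± 0.33, Ckm by 4.2 ± 0.46 and Col10a1 by 4.19 ± 0.37, and bone genes rose in 9 of 13 (median 1.13, adjusted p = 8.4e-09). Epidermis genes rose in 9 of 22, or 10 of 22 adjusted over the list alone (median 0.91, adjusted p = 5.0e-07), adipocyte genes in 6 of 11, or 7 of 11 (median 1.16, adjusted p = 4.4e-10), and intestine genes in 2 of 15 (median 0.34, adjusted p = 0.0014, adjusted p = 0.087 with an estimated correlation). Ppp1r17 fell by 2.24 ± 0.30, the neural factor Tal2 by 1.94 ± 0.29 and Robo3 by 1.94 ± 0.36. Hox paralogues 9 to 13 fell in 3 of 11, or 4 of 11 adjusted over the list alone (median -0.91, adjusted p = 9.6e-07). From E14.5 to E16.5, 506 genes rose and 25 fell, or 848 and 594 with no minimum fold. This was the main step of the epidermis list, of which 18 of 22 rose (median 3.07, adjusted p = 4.2e-10). Hrnr rose by 8.00 ± 0.27 to 11173 ± 241, the hair keratin-associated gene Krtap13 by 7.04 ± 0.43 and Calm4 by 6.04 ± 0.47. Intestine genes rose in 11 of 15 (median 2.00, adjusted p = 1.6e-08) and adipocyte genes in 8 of 11 (median 1.74, adjusted p = 9.0e-12). Hba-x fell by 2.96 ± 0.40, Hmga2 by 1.67 ± 0.22 and Sp5, a target of Wnt signalling, by 1.81 ± 0.29, which with a pseudocount 4 times larger was -0.93 and under 2-fold. Counts at these steps rest on 2 arrays a stage: without E14.5 replicate 2 the first step had 336 calls in place of 512, and without E14.5 replicate 1 the second had 352 in place of 531.

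From E16.5 to E18.5, 494 genes rose and 109 fell, or 1029 and 1194 with no minimum fold. Ucp1 rose from 27.7 ± 20 to 9744 ± 109 (log2 change 7.56 ± 0.49), Flg by 6.22 ± 0.35 and Bpifa2, a salivary secretory protein, by 6.21 ± 0.39. Adipocyte genes rose in 8 of 11 (median 1.81, adjusted p = 9.0e-12), fatty acid oxidation genes in 8 of 14 (median 1.12, adjusted p = 1.8e-09) and intestine genes in 12 of 15, or 14 of 15 adjusted over the list alone (median 1.56, adjusted p = 2.2e-08). Epidermis genes rose in 4 of 22 with 1 fall (median 0.53, adjusted p = 3.7e-05). Erythroid genes fell in 12 of 15 (median -1.56, adjusted p = 1.4e-06) and embryonic globins in 3 of 3 (median -3.69, adjusted p = 1.2e-08). Serpina6 fell by 5.46 ± 0.32, from 6347 ± 94.6 to 122 ± 45.6, Krt77, a keratin of the upper epidermis, by 4.70 ± 0.45 and Krtap13 by 4.38 ± 0.43. Over the 7 steps 176 tests of a list at a step were called, 90 of them with an estimated correlation.

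**Figure D4:**
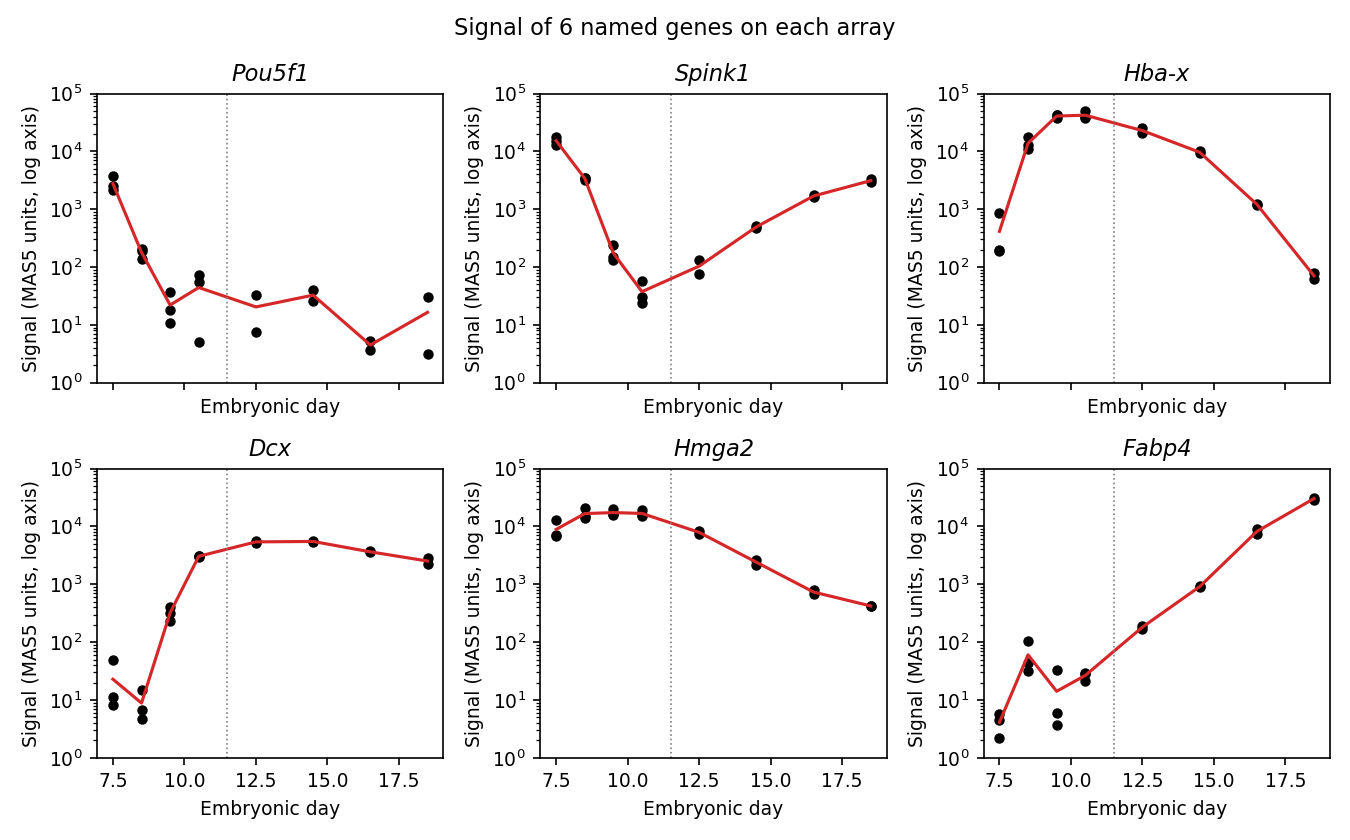
Signal (MAS5 units, log axis) of Pou5f1, Spink1, Hba-x, Dcx, Hmga2 and Fabp4 against embryonic day, with a point for each of the 20 arrays and a line through the stage means; the dotted line separates the array sets. Pou5f1 goes from 2765 ± 824 at E7.5 to 44.3 ± 35.2 at E10.5 and Fabp4 from 26.5 ± 4.30 at E10.5 to 30347 ± 1616 at E18.5.

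The long comparisons meet at E10.5, and some genes were higher or lower there than at both E7.5 and E18.5. The other stages were not part of this test, and Nhlh2, for example, measured 1798 ± 97.2 at E10.5 and 1806 ± 89.9 at E12.5. Among the 335 genes higher at E10.5 than at both E7.5 and E18.5 were the neural factors Neurog1 (13.2 ± 11.9 at E7.5, 885 ± 78.9 at E10.5 and 17.9 ± 4.54 at E18.5), Neurog2, Nhlh2 and Rfx4, the retinoic acid binding Crabp1, the embryonic globin Hba-x, and Ppp1r17, Lix1, Pantr1 and Hoxb5os. Among the 504 genes lower at E10.5 than at both were Apoc2 (14042 ± 620.2, 51.9 ± 37.2 and 5073 ± 809), Spink1, Fabp1, the glucose transporter Slc2a2, the galectins Lgals3 and Lgals2, the calcium-binding S100g, the tight junction protein Cldn2, Vil1 and Dram1. Independent lists of these sizes would share 282.3 genes that were higher (2251 and 1761 genes of 14044) and 253.3 that were lower (1052 and 3381). Both comparisons use the 3 arrays of E10.5. Dividing these 1 and 2 between the comparisons, a test chosen after the data were seen in which a lone array is assumed to vary like the others, can be done in 6 ways. These gave 313 to 345 higher, where independent lists share 269.0 to 317.3, and 458 to 533 lower, where they share 237.5 to 269.1. In 20 simulated sets unchanged genes were held to the p-values and folds of the observed calls. A mean of 2.5 (highest 8) were higher and 2.3 (highest 5) lower, and these values leave out the real changes. The E18.5 side of both groups crosses the array sets. The E7.5 side of the lower group may include extraembryonic tissue in the E7.5 samples, whose amount was not tested. For genes of such tissue, a change in the tissue collected and a change in expression cannot be told apart there.

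Genes that differ between the sexes moved between stages. The labels give no number of males per pool. A change with stage and a different share of males in the pools therefore cannot be told apart here. The Y-linked Eif2s3y, Kdm5d and Uty, expressed only in males, all fell from E9.5 to E10.5 (list median -1.53, adjusted p = 0.0011, adjusted p = 0.11 with an estimated correlation) and all rose from E10.5 to E12.5 (list median 1.28, adjusted p = 0.0041, adjusted p = 0.44 with an estimated correlation). Eif2s3y went from 607 ± 172 at E9.5 to 157 ± 117 at E10.5 and 532 ± 31.1 at E12.5. Xist, the RNA of the inactive X in females, rose by 2.01 ± 0.33 from E9.5 to E10.5 (adjusted p = 2.2e-04), against the Y-linked genes. It also rose by 1.22 ± 0.37 from E10.5 to E12.5 (0.011), where they rose too. It fell by 1.15 ± 0.33 from E8.5 to E9.5 (0.020) and by 1.41 ± 0.41 from E16.5 to E18.5 (0.022). None of the 3 Y-linked genes was called at these steps, though Eif2s3y was at the latter after quantile normalization (log2 change 1.23, adjusted p = 0.011). The mean signals of all 3 were still higher at the later stage of both steps, against Xist. Eif2s3y went from 353 to 607 and from 486 to 990, Kdm5d from 264 to 489 and from 250 to 388. Uty went from 156 to 251 and from 213 to 367. The Xist call from E10.5 to E12.5 ended with scaling by the 75th percentile (log2 change 0.96) and without E10.5 replicate 2 (0.94) or E12.5 replicate 2 (adjusted p = 0.068). From E16.5 to E18.5 it ended with any 1 of the 4 arrays left out (0.088 to 0.12). From E8.5 to E9.5 it ended with the mean of all probe sets (log2 change -0.84), arrays numbered 2 and 3 only (-0.60), only the first array set (adjusted p = 0.056) or the 2 stages (0.071), and without 4 of the 6 arrays in turn (0.066 to 0.13). The Y-linked list fell from E7.5 to E10.5 with 1 of 3 genes called (median -0.61, adjusted p = 0.027, adjusted p = 0.55 with an estimated correlation), and with only the first array set in the fit its adjusted p was 0.076. That call also ended with the mean of all probe sets (0.055), with arrays numbered 2 and 3 only (0.25), and without E7.5 replicate 3 (median -0.58, adjusted p = 0.065) or E10.5 replicate 1 (-0.29, 0.17) or 3 (-0.43, 0.086). It rose from E10.5 to E18.5 with 3 of 3 called (median 1.75, adjusted p = 2.7e-04, adjusted p = 0.39 with an estimated correlation) and was not called from E12.5 to E18.5 (median 0.46, adjusted p = 0.29). With only the second array set in the fit it was called there (8.4e-04). Calls of single Y-linked genes ended in many settings, given here with the log2 change where it was under 2-fold. From E10.5 to E12.5 Kdm5d was not called after quantile normalization (0.63) or scaling by the 75th percentile (0.95), with a pseudocount 4 times larger (0.87), with the mean of all probe sets (0.80) or without E10.5 replicate 1 (0.75). Nor was it called with only the arrays of the 2 stages (adjusted p = 0.055) or without E12.5 replicate 1 (0.054) or 2 (0.066). Uty was not called at that step after quantile normalization (0.64), with the larger pseudocount (0.86), or without E10.5 replicate 1 (0.97) or E12.5 replicate 1 (adjusted p = 0.072). From E9.5 to E10.5 Uty was not called with the mean of all probe sets (-0.65), the larger pseudocount (-0.80) or without E10.5 replicate 1 (-0.89). The same held with only the arrays of the 2 stages (adjusted p = 0.054) and without E9.5 replicate 3 (0.063) or E10.5 replicate 3 (0.061). Kdm5d was not called there with arrays numbered 2 and 3 only (-0.94). From E10.5 to E18.5 Kdm5d was not called after quantile normalization (0.72), with the larger pseudocount (0.93), with the mean of all probe sets (0.94) or without E10.5 replicate 1 (0.82). Calls were gained by Kdm5d from E8.5 to E9.5 without E9.5 replicate 2 (1.07), by Kdm5d (-1.05) and Uty (-1.12) from E7.5 to E10.5 without E10.5 replicate 2, and by Eif2s3y from E12.5 to E18.5 after quantile normalization (1.10).

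Common reference genes were not called from E10.5 to E18.5 (median -0.30, adjusted p = 0.996, with the test in the other direction), while scaling by the 75th percentile gave a median of -0.51 (adjusted p = 0.0083) and quantile normalization 0.06 (6.7e-05). The list rose on balance from E12.5 to E18.5 with 1 rise and 1 fall in 12 (median 0.36, adjusted p = 2.8e-05, adjusted p = 0.28 with an estimated correlation). Among them B2m, a part of the MHC class I complex, rose by 1.56 ± 0.12 and Polr2a, the large subunit of RNA polymerase II, fell by 1.19 ± 0.25, or by 0.90 and under 2-fold as the mean of its probe sets.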

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

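The tests of the hybridisation controls, of the gradual gain, of the receptors with an array left out and of the share of rises after quantile normalization were chosen after the result was seen. Control probe sets, which no comparison uses, gave a pair of signals. The poly-A control dap read 1985 or more on each array of E12.5 to E18.5 and 123 or less on each array of E7.5 to E10.5. The 5' probe set for 18S ribosomal RNA read 19203 on E14.5 replicate 1, against 5001 on the next highest array.

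From E10.5 to E12.5 rises outnumbered falls, and the median signal of an array rose by 0.85 on the log2 scale. A gradual gain of transcripts with age is argued against as the whole cause, since that median changed by only 0.12 from E12.5 to E18.5, but it climbed from 6.10 through 6.23 and 6.26 to 6.44 from E7.5 to E10.5, so a part stays open. A weaker spread at hybridisation is argued against for the Cre and BioB controls alone. Their log2 difference was 5.01 to 5.36 on the late arrays (median 5.15) and 4.83 to 5.42 on the early ones (median 5.13). They do not cover the whole range of signals, which was narrower on the late arrays. The 25th percentile of an array had a median of 45.6 on the late arrays and 22.2 on the early ones. The highest signal had a median of 37311 on the late arrays and 55021 on the early ones. Higher signal on probe sets for genes not expected in embryos stays open. The median of 84 sensory receptor probe sets changed by 0.29, under the 0.37 of the largest step inside a set. With an array left out in turn, that largest step was 0.17 (without E16.5 replicate 2) to 0.80 (without E16.5 replicate 1). The change between the sets was then 0.20 (without E12.5 replicate 2) to 0.42 (without E10.5 replicate 2), so the comparison turns on single arrays. A different signal distribution of the array sets stays open: the share of rises dropped from 83.9% to 58.4% after quantile normalization and to 51.3% with scaling by the 75th percentile, but both would lower it whether the shift were technical or biological, and the array set and the stage cannot be told apart here, so a real difference between E10.5 and E12.5 stays open, as untested.

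For comparisons of 3 arrays with 3, the counts were set against the other ways to split the same 6 arrays. Only 1 of 10 splits, the real one, gave as many calls in each: 1574 genes for E8.5 against E7.5 (highest other 1), 585 for E9.5 against E8.5 (2), 514 for E10.5 against E9.5 (3), 3303 genes for E10.5 against E7.5 (1) and 32 gene lists there (0). With 10 splits the share cannot fall under 0.05. Each other split mixes both stages in each group, so a difference between stages enlarges the spread within groups and leaves few calls. The low counts of the other splits are therefore no separate evidence.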

How the results depend on the processing

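Fits of a single array set, fits of arrays numbered 2 and 3 only, the Mantel tests of parts of the series and the comparison of E18.5 with E12.5 were chosen after the result was seen. Results that ended or moved follow by setting, and unless a cause is named it was not tested.

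With a pseudocount 4 times larger, which shrinks changes of dim genes, calls numbered 855 at E8.5, 266 at E9.5, 209 at E10.5, 914 at E12.5 and 340 at E14.5, each against the stage before, 2141 for E10.5 against E7.5, and 281 genes lower at E10.5 than at both ends. With the stricter filter, which tests fewer genes, they numbered 331 for E10.5 against E9.5, 1027 for E12.5 against E10.5, 2156 for E10.5 against E7.5, 3331 for E18.5 against E10.5, 1966 for E18.5 against E12.5, 6095 in the F test and 307 lower at E10.5. With no minimum fold the steps had 5329, 2309, 2640, 6665, 1463, 1442 and 2223 calls in order of age, the long comparisons 8150 (E10.5 against E7.5), 9758 (E18.5 against E10.5) and 7465 (E18.5 against E12.5), and 1733 genes were higher and 1250 lower at E10.5. Camera estimates the correlation between genes and also compares a list with the other genes. It called 15 lists in place of 32 for E10.5 against E7.5, 22 in place of 35 for E18.5 against E10.5, and 90 in place of 176 at the steps. The Mantel r was 0.92 for E7.5 to E10.5 alone and 0.99 for E12.5 to E18.5 alone (exact p = 0.083 each), where 4 stages allow no smaller p.

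Reversed were the trophoblast list for E18.5 against E10.5 after quantile normalization (median 0.084), fatty acid oxidation for E10.5 against E7.5 (0.10) and common reference genes for E18.5 against E10.5 (-0.51) with scaling by the 75th percentile, pancreas for E10.5 against E7.5 with the stricter filter (0.017), and immediate early and heat shock genes for E10.5 against E7.5 with camera (0.062). In each the direction of the test turned.

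Leaving out an array in turn, where a stage left with 1 array is assumed to vary like the others, gave 336 to 378 calls for E14.5 against E12.5 (512 with all arrays, lowest without E14.5 replicate 2) and 352 to 407 for E16.5 against E14.5 (531, lowest without E14.5 replicate 1). The other counts stayed within 1.5 times. Of the tests of single lists without an array, 545 stayed on their side of the threshold, 15 lost and 3 gained a call and 7 uncalled values moved; of named genes 2550 stayed, 46 lost and 3 gained a call and 6 moved. After quantile normalization 506 of 520 named changes kept direction and call.

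The labels give equal replicate numbers no shared source, so the numbers were not taken to pair the samples. Deviations from the stage mean correlated at -0.07 to 0.28 over 62 pairs of arrays with equal numbers, 13 of them above 0.1, and at -0.21 to 0.10 over 112 pairs with different numbers. All 6 pairs of first-numbered arrays of E7.5 to E10.5 lay at 0.14 to 0.28, a hint from the data at a shared source in the first set. Over both sets, 14 of 20 arrays had their best match in another stage at the same number. Deviations of the arrays of a stage offset each other, so these pairs and matches are not independent. How many matches would arise by chance was not computed. With the replicate number as a block the steps had 1579, 588, 522, 1911, 525, 551 and 623 calls, the long comparisons 3307, 5214 and 3059, and lists 31, 34, 34 and 180 (at the steps). Of the lists called in the long comparisons, the block left out only Y-linked for E10.5 against E7.5 (adjusted p = 0.0501) and trophoblast for E18.5 against E10.5 (0.060). Fits of a single array set gave 1548, 549, 455, 640, 671 and 725 calls at the steps within the sets, 3279 for E10.5 against E7.5 and 3093 for E18.5 against E12.5. Arrays numbered 2 and 3 only gave 1695, 649 and 670 at the early steps and 3373 for E10.5 against E7.5. In simulated data 23 of 67 genes with a 2-fold change and 66 of 67 with a 4-fold change were called for E10.5 against E7.5, so changes near 2-fold are often missed. The simulated 2-fold change lies on the fold cutoff of a call, so estimates just under it are lost whatever their p-value.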

Other observations

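The genes of a short rise at E16.5, their simulation and the division of their arrays, the profiles of Serpina6 and Prl8a2 and the test of 3' to 5' ratios were chosen after the result was seen. A group of 11 genes rose from E14.5 to E16.5 and fell from E16.5 to E18.5. Krt77, a keratin of the upper epidermis, measured 241 ± 29.5, 6119 ± 149 and 211 ± 14.4 at E14.5, E16.5 and E18.5 (SD, n = 2), and Krtap13, a hair keratin-associated protein, 30.4 ± 5.16, 7339 ± 91.6 and 329 ± 43.7. Dynap, Mal, Ugt2b36, Upk3bl and Irs4 also followed this course. Independent lists of 506 rises and 109 falls would share 3.93 genes, and 3 genes took the opposite course. In 20 simulated sets of unchanged genes held to the p-values and folds of these calls, a mean of 1.5 (highest 4) had the short rise, a value that leaves out the real changes. The comparisons share the arrays of E16.5. With these divided between them, 1 array each, 8 and 9 genes had the short rise in the 2 ways to do so, where independent lists would share 2.70 and 2.30.

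Serpina6, the plasma carrier of corticosteroids, measured 2111 to 2252 at E12.5, 6798 to 7736 at E14.5, 6280 to 6414 at E16.5 and 90.0 to 154 at E18.5. Prl8a2, a prolactin of the maternal decidua, measured 648 to 1263 at E7.5, 747 to 2661 at E8.5 and 20.4 to 53.2 at E9.5.

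Y-linked transcripts differed between arrays of the same stage. Eif2s3y measured 120, 289 and 63.3 on the arrays of E10.5, where Xist measured 3472, 1670 and 2599. A different share of male embryos in the pools may account for this: over 20 arrays, deviations from the stage mean of the Y-linked genes and of Xist correlated at r = -0.65 (one-sided permutation p = 0.021, rho = -0.76, p = 0.014), and at -0.60 without E10.5 replicates 1 and 2. The 3 Y-linked genes correlated with each other at 0.63 to 0.76. The labels give no number of males per pool, so this remains a hypothesis.

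The first-numbered arrays of E7.5 to E10.5 deviated together from their stage means, with correlations of 0.14 to 0.28 across stages. A different share of male embryos could not be decided: the Y-linked mean lay above the stage mean on 1 of these 4 arrays and below it on 3, each time by less than the SD of the stage. RNA quality, read as the ratio of 3' to 5' control signals, could not be decided: those of E8.5, E9.5 and E10.5, 3 of the 4, had the lowest ratio of their stage, and that of E7.5 had the highest. No other biological explanation was tested.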
